A study of Mus musculus with 36 samples.

How the data were processed

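Gene expression was measured with Affymetrix mouse arrays in cerebellum, midbrain and striatum of mice of 2 genotypes at 2 ages. The double mutant mice lacked Pink1, which encodes a mitochondrial kinase, and carried A53T-SNCA, a human alpha-synuclein transgene with a mutation found in familial Parkinson disease. The wild type controls were F1 hybrids of the 129SvEv and FVB/N strains, per the labels. Each of the 12 groups held 3 arrays, which made 36 in all. Per the labels' protocols, RNA was extracted with a column kit and biotin-labelled cRNA was prepared from 100 ng total RNA with a 3' in vitro transcription kit.

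The deposited values were log2 expression values, 1 for each of 45141 probe sets on each array. Per the submitters' processing notes they were made with RMA in R 2.12.0, which corrects background, normalises quantiles and summarises probes on the log2 scale. The notes did not say whether all 36 arrays were normalised in 1 run. Array medians lay between 4.37 and 4.47 and the values ran from 1.99 to 13.54. Raw probe intensities were not available, so the background step could not be varied. Array data have no read depth, and the number of arrays per group limits the precision.

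The 104 Affymetrix control probe sets were left out, which left 45037 for testing. Gene names came from the platform's annotation table. It paired 28898 of all probe sets with 1 gene symbol and 551 with several, and did not list 15588, which are called unnamed here. No gene was named from a probe set with several symbols. Entrez identifiers of 28689 probe sets were found in the mouse reference gene table (assembly GRCm38.p6), and 0 symbols needed updating. That table was used for names and for the order of neighbouring genes alone. For each of 17097 genes, the probe set with the highest mean over all arrays represented the gene.

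A linear model with 1 mean per group was fitted to all 36 arrays with limma 3.58.1 in R 4.3.3 (lmFit and eBayes without an intensity trend), so that the 12 groups shared 1 estimate of the spread per probe set. The fit had 24 residual and 4.8 prior degrees of freedom. The p-values were adjusted by the Benjamini-Hochberg method over all probe sets tested, and the threshold was an adjusted p of 0.05. Unless another test is named, each adjusted p of a gene comes from this fit and is two-sided. Genotype differences are double mutant minus wild type on the log2 scale. Age differences are 6 months minus 6 weeks. The age by genotype interaction is the genotype difference at 6 months minus that at 6 weeks, and the tissue by genotype interaction is an F test that the genotype difference, averaged over ages, is equal in the 3 tissues. The number after ± is a standard error (SE) unless a standard deviation (SD) is named, and the SE of a fitted difference uses the pooled spread. The deposited values held no detection calls, so a group mean below the median of 4.49 over probe sets was not shown to lie above background, and the size of a difference with such a mean is uncertain.

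The comparisons, the test, 34 gene lists and the rule for named genes were fixed before the data were examined. The rule takes genes with a representative probe set past the threshold. For the averaged genotype difference it takes the 12 largest rises and 12 largest falls with 1 sign in all 6 combinations of tissue and age. For each combination it takes up to 6 rises and 6 falls in which the 3 double mutant arrays lie on 1 side of the 3 wild type arrays, leaving out genes named in the average. It takes up to 4 of each sign for each age by genotype interaction, the 8 smallest p for the tissue by genotype interaction, and 6 rises and 6 falls for each age difference in wild type. For a gene list it takes up to 4 members with the largest absolute changes. Members outside these 4 that passed the threshold, such as Homer1 and Ndufs4 in the average, were named after their values were seen, and so were genes beside Pink1. The lists held 614 entries, of which 532 were measured. The sex chromosome list was read as values only, and the other 33 lists were tested with limma's camera on the representative probe sets with a preset inter-gene correlation of 0.01. Adjustment ran over 231 tests for the genotype differences and over 99 for the age differences in wild type. The same tests were repeated with a correlation estimated from the residuals.

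The scripts were tested on simulated data for all 45037 probe sets, with 200 of them changed, all drawn from those with a mean above the median. The shares recovered therefore do not cover dim probe sets. For the averaged genotype difference 100% of the probe sets changed 1.5-fold were recovered, and 18 of 218 calls were false. In the single combinations of tissue and age the share recovered at 1.5-fold lay between 75.3% and 80.8%, at 2-fold between 98.4% and 100%, and false calls numbered 2 to 15 in each. With no interaction simulated, each interaction test made 0 calls. A list shifted by 0.2 in the averaged comparison, the proteasome list, was found with an adjusted p of 1.33e-174, and 0 other lists were called. The simulated noise was independent between genes, so it could not show false calls of lists whose members are correlated. It was also independent between arrays, so it could not show false interaction calls from deviations that arrays share.

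Alternatives tried were a filter on dim probe sets (mean above the median of 4.49), quantile normalisation over all 36 arrays, eBayes with a trend and robust prior, a 1.5-fold minimum change, only the arrays of the groups compared, replicate number as a block, leaving out each array of the groups compared in turn, and, for list tests, the mean over all probe sets of a gene. Fits without the arrays with a strong Xist signal, fits with that signal as a covariate, list tests without the genes beside Pink1, and renormalised tissue markers were added after the data were seen. The dim filter removed some named genes, whose values were not all shown to lie above background. For genotype differences these were Klk1b9, Vmn2r29, Zcwpw2, Mgl2, BC062258, Alox8, Fads2b, Sh2d6, Spint1 and Galnt15. Others were Car9, Ccl28, Agtr2, Gbp2b, Aplnr, Gm9895, Pnmt, Smpdl3b, 2610528A11Rik and C030013G03Rik. For interactions they included Masp2, Gm8369, Psors1c2 and Nr0b2. For age they were Ltbp2, Mkrn3, Exoc3l4, Mvp, 9630013A20Rik, Rspo1, A230009B12Rik and Tcfl5. Neighbouring genes were counted with 10000 random gene sets of the same size among the 16935 genes that could be placed in order. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.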

Results

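The data were log2 expression values from 36 arrays, with 3 arrays in each of the 12 groups formed by 3 tissues, 2 genotypes and 2 ages. Arrays of the same group correlated with r between 0.9934 and 0.9969 across probe sets. The first principal component carried 56.5% of the variance and the second 27.4%, and together they separated the tissues. The design asks what loss of Pink1 together with A53T-SNCA changes in each brain region at 6 weeks and at 6 months.

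Markers of each region followed the tissue labels in wild type arrays. Of 19 measured dopaminergic neuron genes, 13 were higher and 3 lower in midbrain than in the other tissues, with a median difference of 1.19. The dopamine transporter gene Slc6a3 was higher by 5.07 ± 0.073, the decarboxylase gene Ddc by 3.71 ± 0.095 and the tyrosine hydroxylase gene Th by 2.98 ± 0.128. Of 15 medium spiny neuron genes, 14 were higher in striatum, with a median of 4.23 and Drd1, a dopamine receptor, at 7.26. Of 15 cerebellar neuron genes, 14 were higher in cerebellum, with a median of 4.46 and the Purkinje cell gene Pcp2 at 8.26.

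Pink1, the disrupted gene, was far lower in every double mutant group. Averaged over tissues and ages, the probe set with the stronger signal fell by 3.80 ± 0.044, which is 13.9-fold, from a wild type mean of 10.30 ± 0.21 (SD, n = 18) to 6.50 ± 0.16 (SD, n = 18), with an adjusted p of 1.55e-31. Across the 6 combinations of tissue and age its difference lay between -3.55 and -4.03. The other Pink1 probe set fell by 4.04 ± 0.066, or 16.4-fold, with differences between -3.61 and -4.66. The highest double mutant array was at 6.8 on the first probe set and the lowest wild type array at 9.93. Probe sets for Snca, Prnp and Ddx3y were not named in the annotation table, so the transgene was not checked.

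**Figure D1:**
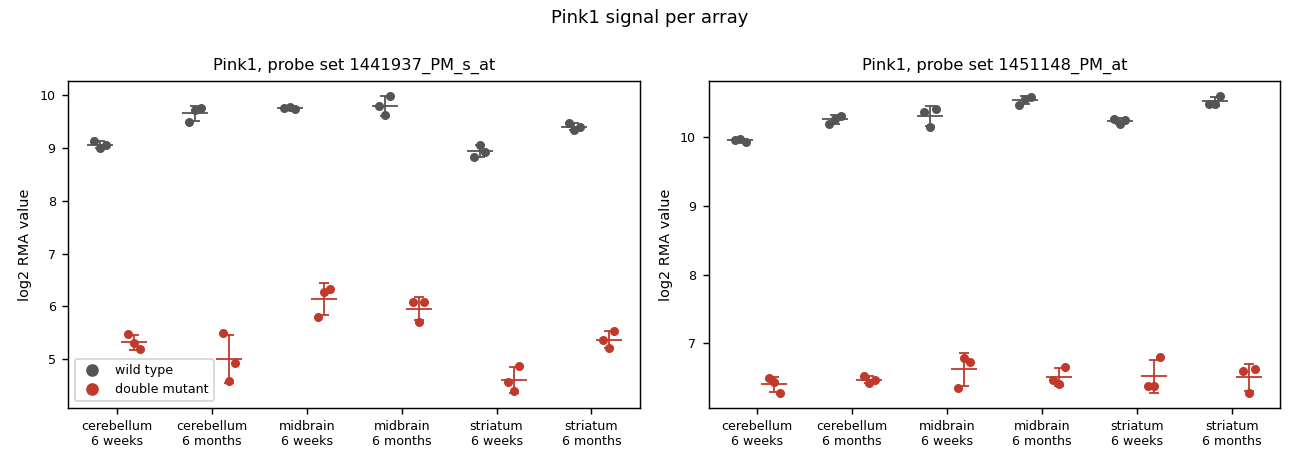
Pink1 on its 2 probe sets, with the log2 RMA value of each array on the vertical axis and tissue and age on the horizontal axis. Points are arrays, horizontal marks are means and bars are SD (n = 3). On the probe set with the stronger signal the double mutant arrays reached at most 6.8 and the wild type arrays at least 9.93.

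Averaged over the 3 tissues and 2 ages, the genotypes differed at many genes, most of them by modest amounts. Beyond Pink1 the largest falls were in the kallikrein protease gene Klk1b9 (-2.16 ± 0.191), 2010315B03Rik (-2.07 ± 0.080), the secreted protein gene Cthrc1 (-1.63 ± 0.254), the RNA-binding protein gene Rbm45 (-1.33 ± 0.067), the meiotic recombination gene Psmc3ip (-1.20 ± 0.151), Lars2, the mitochondrial leucyl-tRNA synthetase (-1.11 ± 0.045), and the growth factor gene Fgf1 (-1.01 ± 0.267). The largest rises were in Far2, a fatty acyl-CoA reductase (0.92 ± 0.049), the interferon-inducible gene Xaf1 (0.88 ± 0.043), Dynlt1b, a dynein light chain (0.88 ± 0.054), 2700081O15Rik (0.81 ± 0.056) and C920006O11Rik (0.80 ± 0.068). Klk1b9 fell most in cerebellum, by 4.26 at 6 weeks and 3.86 at 6 months. Its mean over all arrays was not above 4.49, so its values were not all shown to lie above background. The size of its fall is therefore uncertain. Differences of 2-fold or more were seen in 63 of the probe sets past the threshold, whose median absolute change was 0.249, and 221 changed at least 1.5-fold.

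In total 1989 probe sets passed the threshold in the average, 910 higher and 1079 lower in double mutants, and 759 genes did so by their representative probe set, 338 higher and 421 lower. Further rises were in Tmem181c-ps (0.79), Trim13, a ubiquitin ligase (0.71), the muscle Z-disc gene Ldb3 (0.66), the histone RNA processing gene Lsm11 (0.65), the interferon-induced gene Ifit3 (0.64), Erdr1 (0.63) and Npas4, a transcription factor induced by neuronal activity (0.62 ± 0.153, adjusted p = 0.0115, or 0.0807 without the arrays with a strong Xist signal). Further falls were in 4632427E13Rik (-0.96), A330076H08Rik (-0.93), Zfp939 (-0.93) and the vomeronasal receptor gene Vmn2r29 (-0.92). The mean of Vmn2r29 over all arrays was not above 4.49 either, so the size of its fall is uncertain. The adjusted p of Fgf1 was 0.0213, and those of the other genes named here lay below that of Npas4. Not all probe sets of a gene moved together. A further Xaf1 probe set was past the threshold in the opposite direction, a further one of Far2 was not past it, and 221 called probe sets belonged to genes whose representative had an unadjusted p of 0.05 or more.

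The differences were shared between tissues and ages. Of the 1989 probe sets, 1388 (69.8%) had 1 sign in all 6 combinations of tissue and age, against 3.12% for independent random signs, although the average itself favours such probe sets. Tested singly, 89 probe sets passed the threshold in all 6 combinations, 32 higher and 57 lower, of which 39 were unnamed. The 25 genes among them included, besides Pink1, Rbm45, Lars2, Far2 and Xaf1, the mitochondrial proline-degrading enzyme gene Aldh4a1 (-0.88 ± 0.061), the kinase gene Dapk1 (-0.73 ± 0.049), the malic enzyme gene Me1 (0.53 ± 0.038) and Ndufv1, a core subunit of respiratory complex I (0.41 ± 0.032). Any 2 combinations, which share no array, had between 149 and 212 probe sets past the threshold in the same direction, against 1.01 to 4.37 for independent lists, and at most 3 in opposite directions. The lists were not independent, since they share 1 estimate of the spread per probe set. Double mutant arrays with the same number also deviated together across tissues, so the expected numbers are only a rough reference. Aldh4a1, Me1, Dapk1 and Ndufv1 were chosen from the 25 after their values were seen.

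Genes past the threshold in the average lay near one another along the chromosomes. Of the 752 that could be placed in order, 60.2% had another among the 5 nearest measured genes on either side, against a median of 36.3% in random gene sets, of which 0.1% exceeded 43.2%. Among the 50 measured genes on each side of Pink1, 13 of 100 were past the threshold, against 738 of 16834 elsewhere (4.38%). These 13 included Aldh4a1, the complement genes C1qb (0.36 ± 0.044) and C1qc (0.38 ± 0.049), the actin capping gene Capzb (0.23 ± 0.021), and Ddost (0.17 ± 0.025), which lay next to Pink1.

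**Figure D2:**
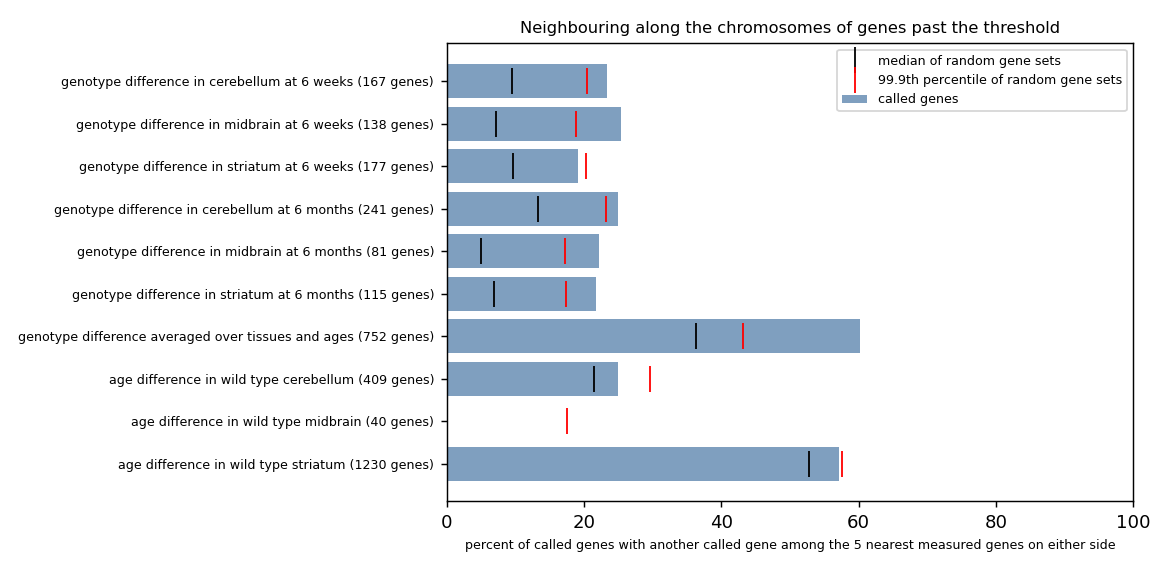
Share of the genes past the threshold that had another such gene among the 5 nearest measured genes on either side, in percent, for each comparison (bars), with the median (black) of random gene sets of the same size and the value that 0.1% of them exceeded (red). For the averaged genotype difference the share was 60.2% against 43.2% at the red mark, and for the age difference in wild type cerebellum it was 24.9% against 29.6%.

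By gene list, 3 lists were higher and 1 was lower in double mutants in the average, and 3 of these 4 held with replicate number as a block. Of 17 microglia genes 4 rose (4 adjusted over the list alone), namely C1qc (0.38), C1qb (0.36), Fcrls (0.27) and the protease gene Ctss (0.26), with a list median of 0.053 and an adjusted p of 0.00768, which became an adjusted p of 0.908 with an estimated correlation. C1qa, C1qb and C1qc are among the 50 measured genes on each side of Pink1, and without these 3 members the median was 0.038 and the adjusted p was 0.2. Of 20 immediate early genes 2 rose and 1 fell (8 and 2 adjusted over the list alone). Npas4 was higher by 0.62 and Homer1, a postsynaptic scaffold, lower (-0.24), and the list had a median of 0.119 and an adjusted p of 0.00768 (adjusted p = 0.954 with an estimated correlation). At 6 months the list mean of double mutant replicate 1 lay within those of the wild type arrays in cerebellum (6.70) and below them in midbrain (6.45) and striatum (7.66). Of 15 cholesterol synthesis genes 2 rose, Hmgcs1 (0.29 ± 0.070) and Sc5d (0.12 ± 0.033), and 1 fell, Dhcr7 (-0.18 ± 0.050), with 3 and 1 adjusted over the list alone, a median of 0.059 and an adjusted p of 0.0442 (adjusted p = 0.954 with an estimated correlation). Of 12 mural and meningeal fibroblast genes 1 fell, the pericyte gene Rgs5 (-0.18 ± 0.027), with 2 falls adjusted over the list alone, a median of -0.104 and an adjusted p of 0.0148 (adjusted p = 0.908 with an estimated correlation).

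Several lists related to Parkinson disease were not past the threshold in the average. The dopaminergic neuron list had a median of 0.039 and an adjusted p of 0.183, with 1 of 19 genes higher, Aldh1a1 (0.22 ± 0.031). Mitophagy and autophagy genes had a median of -0.011 (adjusted p = 0.815, 0 of 21 past the threshold), Parkinson disease genes -0.015 (adjusted p = 0.948, 0 of 15) and synaptic vesicle genes -0.002 (adjusted p = 0.709, 0 of 23). Proteasome genes had a median of -0.005 (adjusted p = 0.811), with Psmb2 higher by 0.09 ± 0.024, and 14-3-3 genes a median of 0.019 (adjusted p = 0.169), with Ywhaz higher by 0.16 ± 0.033. Among respiratory complex I genes Ndufv1 rose, while Ndufs4 (-0.14 ± 0.028) and Ndufb8 (-0.10 ± 0.022) fell, and the list had a median of -0.016 (adjusted p = 0.204). The list of respiratory complexes II to V was not called with all its members. Without its 1 member beside Pink1 it was lower, with a median of -0.02 and an adjusted p of 0.0499 at the preset correlation. The interferon response list had a median of 0.013 (adjusted p = 0.093), with Xaf1, Ifit3 and Stat2 (0.14 ± 0.036) higher among 15 genes.

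**Figure D3:**
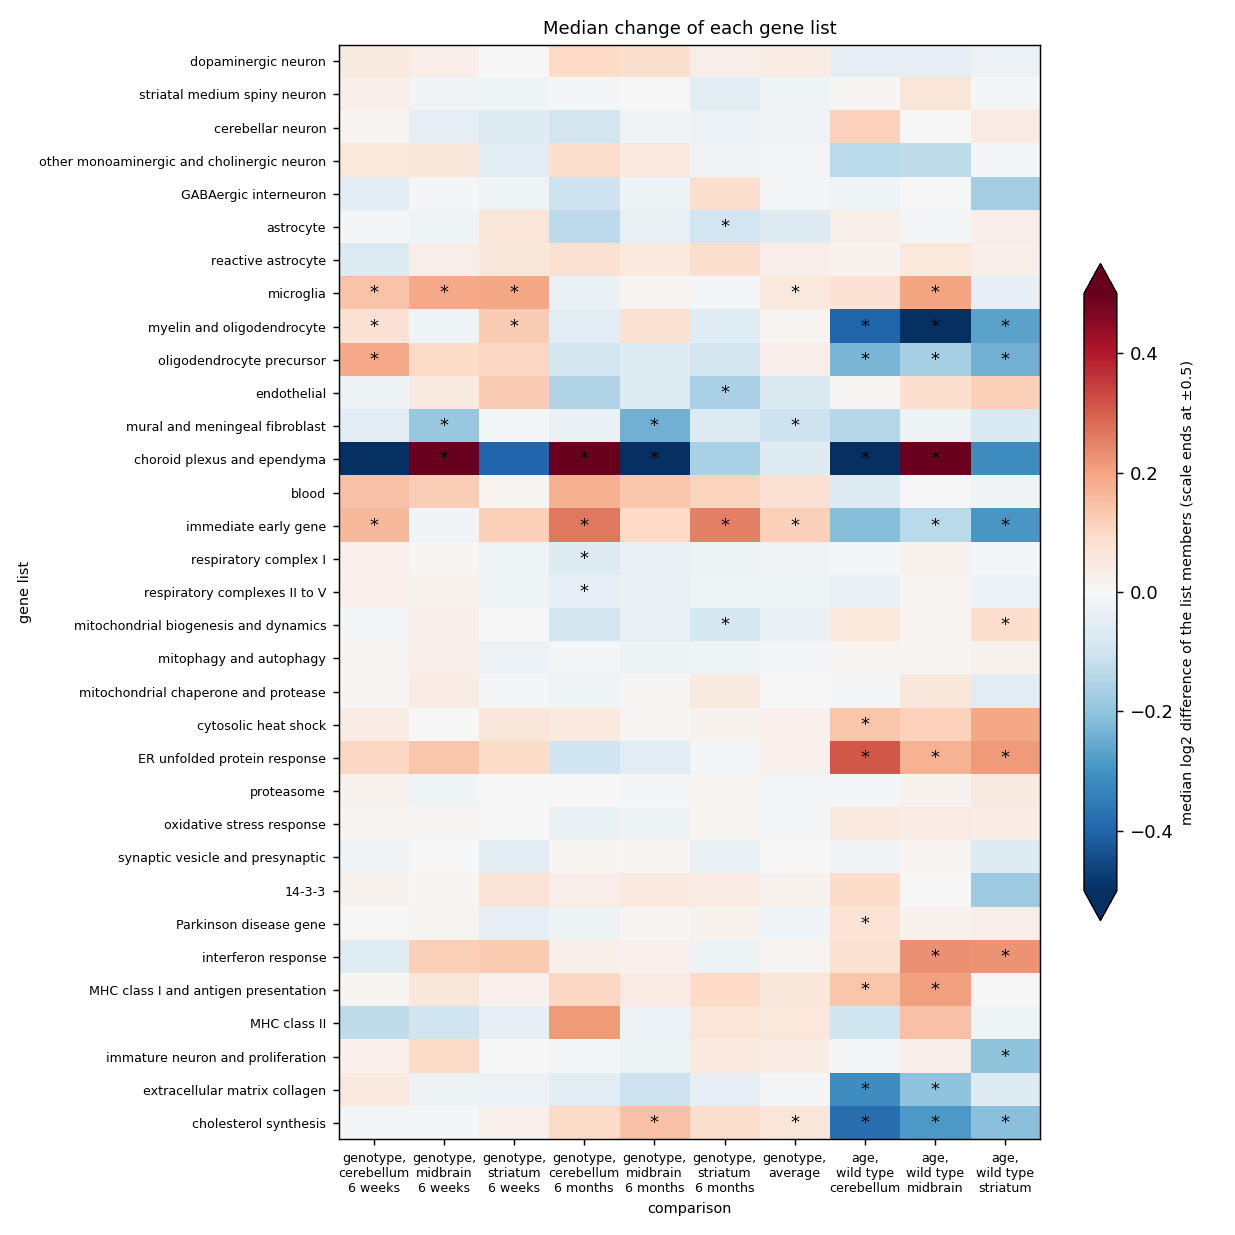
Median log2 difference of the measured members of 33 gene lists (rows) in 7 genotype comparisons and 3 age comparisons in wild type (columns). Red is higher and blue lower in double mutants or at 6 months, and asterisks mark lists with an adjusted p under 0.05 at the preset correlation. The myelin list had medians of -0.399, -0.519 and -0.268 with age in wild type cerebellum, midbrain and striatum.

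In cerebellum at 6 weeks the genotypes differed most, beyond the shared genes, in Kbtbd11, a BTB-kelch family gene, which was lower in double mutants (-2.55 ± 0.274, from 8.21 ± 0.06 to 5.66 ± 0.67, SD, n = 3). Its other probe set, of low signal, was not past the threshold in any combination of tissue and age (-0.31 here, adjusted p = 0.631). Lower too were the death-associated protein gene Dap (-1.29), Cep83os (-1.26), Caprin2 (-1.11), Gm5817 (-1.06) and Aldh4a1 (-1.01), with SE from 0.111 to 0.211. Higher were Zcwpw2 (0.98), the macrophage lectin gene Mgl2 (0.92), Rragd, a GTPase of amino acid sensing (0.92), Cyb5d2 (0.79), the endoplasmic reticulum transcription factor gene Creb3 (0.79) and the growth factor gene Bmp5 (0.75, missed in 1 of 13 alternatives), with SE from 0.079 to 0.151. In all, 484 probe sets passed the threshold, 184 higher and 300 lower, and 168 genes. The count was 299 without wild type replicate 2, 269 with only the 6 arrays compared in the fit and 278 with a 1.5-fold minimum.

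As groups, 4 lists were higher in double mutant cerebellum at 6 weeks, but 0 were called with the mean over all probe sets of a gene. Of 17 microglia genes 1 rose, C1qc (0.50 ± 0.120), with 3 adjusted over the list alone and a median of 0.143 (adjusted p = 0.0312, or an adjusted p of 0.954 with an estimated correlation and 0.267 without the 3 C1q members). Of 20 immediate early genes 1 rose, Junb (0.72 ± 0.181), 1 adjusted over the list alone, with a median of 0.162 (adjusted p = 0.0257, or an adjusted p of 0.954 with an estimated correlation). Of 14 myelin genes 1 rose, Mbp (0.26 ± 0.065), 1 adjusted over the list alone, with a median of 0.072 (adjusted p = 0.0442, or an adjusted p of 0.954 with an estimated correlation). None of 10 oligodendrocyte precursor genes was past the threshold, also when adjusted over the list alone, and the list median was 0.191 (adjusted p = 0.0457, or an adjusted p of 0.908 with an estimated correlation).

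In midbrain at 6 weeks Kbtbd11 was again lower in double mutants (-2.74 ± 0.274, from 6.32 ± 0.26 to 3.58 ± 0.17, SD, n = 3). The lower mean was below the median of 4.49 over probe sets and was not shown to lie above background, so the size of this fall is uncertain. Also lower were the lipoxygenase gene Alox8 (-1.12), Snx29, a sorting nexin (-1.11), Yae1d1 (-1.09), Fads2b (-0.93) and Zfp949 (-0.88), with SE from 0.076 to 0.223. Higher were Fam205a1 (1.12), the matrix protein gene Matn2 (1.07), the formyl peptide receptor gene Fpr2 (1.05), the protease inhibitor gene Slpi (0.92), BC062258 (0.84) and B230311B06Rik (0.83), with SE from 0.119 to 0.233. Of these genes, Snx29 missed the threshold in 4 of 13 alternatives (adjusted p up to 0.235), Fam205a1 in 3 of 13 (0.119), and BC062258 and Fads2b in 2 of 12 each (0.141 and 0.11). In all, 442 probe sets passed the threshold, 191 higher and 251 lower, and 140 genes. The count depended on single arrays: it was 968, 221 and 265 without wild type replicates 1, 2 and 3, 284 and 288 without double mutant replicates 2 and 3, 240 with only the 6 arrays compared in the fit, 280 with a 1.5-fold minimum, and 666 without the arrays with a strong Xist signal.

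Microglia genes were higher as a group in double mutant midbrain at 6 weeks. All 17 had positive differences, and C1qb (0.66 ± 0.108) and Fcrls (0.66 ± 0.165) passed the threshold, or 5 genes adjusted over the list alone. The median was 0.188 and the adjusted p 6.63e-05, or an adjusted p of 0.908 with an estimated correlation. Without the 3 C1q members the median was 0.177 and the adjusted p 0.00814. Mural and meningeal fibroblast genes were lower as a group, with a median of -0.189 (adjusted p = 0.00107, or an adjusted p of 0.908 with an estimated correlation), although 0 of 12 passed the threshold singly, by limma or adjusted over the list alone. Choroid plexus and ependyma genes had a median of 1.07 (adjusted p = 0.00875, or an adjusted p of 0.954 with an estimated correlation) and 0 of 14 passed singly, also adjusted over the list alone. Ttr, the transthyretin gene that choroid plexus expresses strongly, stood at 13.07, 8.80 and 12.78 on the 3 double mutant arrays and at 9.24, 11.21 and 10.82 on the wild type arrays.

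In striatum at 6 weeks the largest difference of a named gene beyond Pink1 was in the glutathione peroxidase gene Gpx6, which was lower in double mutants by 3.74 on the log2 scale (-3.74 ± 0.276, from 8.06 ± 0.23 to 4.31 ± 0.61, SD, n = 3). Next were Cdhr1, a cadherin-related gene (-2.45 ± 0.178), and Kbtbd11 (-2.06 ± 0.274), followed by the peroxisomal racemase gene Amacr (-1.28), Uggt2, a glycoprotein folding sensor (-1.19), and the protease inhibitor gene Spint1 (-1.19). Higher were Sh2d6 (0.95), Lgi3 (0.87), Samd4 (0.84), the gamma-secretase subunit gene Aph1b (0.79), Dock10 (0.79) and Creb3 (0.78), with SE from 0.088 to 0.175. Amacr and Dock10 missed the threshold in 4 of 13 alternatives each (adjusted p up to 0.079 and 0.0928) and Aph1b in 1 of 13 (0.131). In all, 546 probe sets passed the threshold, 257 higher and 289 lower, and 178 genes. The count was 324 without wild type replicate 2, 345 with only the 6 arrays compared in the fit and 300 with a 1.5-fold minimum.

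In double mutant striatum at 6 weeks 2 lists were higher. Of 17 microglia genes C1qc (0.50 ± 0.120) and C1qb (0.42 ± 0.108) rose, with 4 adjusted over the list alone and a median of 0.193 (adjusted p = 0.00768, or an adjusted p of 0.908 with an estimated correlation and 0.0969 without the 3 C1q members). None of 14 myelin genes was past the threshold, also adjusted over the list alone, and the list median was 0.127 (adjusted p = 0.0217, or an adjusted p of 0.954 with an estimated correlation).

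In cerebellum at 6 months the largest fall beyond the shared genes was that of Pxylp1, a phosphatase of proteoglycan synthesis (-1.53 ± 0.191). The largest rise was that of the glycosyltransferase gene Galnt15 (0.95 ± 0.197), both among genes whose arrays did not overlap between genotypes. Lower too were Trpt1 (-0.98), A430033K04Rik (-0.96), the carboxypeptidase gene Folh1 (-0.95), Caprin2 (-0.93) and Dcaf17 (-0.90), with SE from 0.151 to 0.217. Higher were Rragd (0.84), the carbonic anhydrase gene Car9 (0.72), the complement regulator gene Cd59a (0.70), Tmc7 (0.69) and Sytl2 (0.69), with SE from 0.079 to 0.158. Sytl2 and A430033K04Rik missed the threshold in 4 of 12 alternatives each, Dcaf17 in 2 of 12 and Caprin2 in 1 of 12. In all, 711 probe sets passed the threshold, 269 higher and 442 lower, and 242 genes. The count was 439 and 406 without double mutant replicates 2 and 3, 348 and 377 without wild type replicates 2 and 3, 211 with only the 6 arrays compared in the fit, and 292 with a 1.5-fold minimum.

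Respiratory chain genes were slightly lower as groups in double mutant cerebellum at 6 months. Of 31 complex I genes 27 had negative or zero differences, the median was -0.066 and the adjusted p 0.0217 (adjusted p = 0.954 with an estimated correlation). Singly Ndufv1 rose (0.41 ± 0.078) against the list, with 1 rise and 1 fall adjusted over the list alone. Complexes II to V had a median of -0.04 over 36 genes (adjusted p = 0.0257, or an adjusted p of 0.908 with an estimated correlation), with 0 past the threshold by limma or adjusted over the list alone. Immediate early genes had a median of 0.263 with 16 of 20 positive (adjusted p = 0.00084, or an adjusted p of 0.908 with an estimated correlation). None passed singly and 4 did adjusted over the list alone, with Npas4 at 1.11 ± 0.375 and Fos at 0.77 ± 0.293. The list means per array were 6.70, 7.28 and 7.41 in double mutants and 6.95, 6.69 and 6.77 in wild type, so double mutant replicate 1 lay within the wild type values and the difference came from the other 2 arrays. The choroid plexus list had a median of 1.065 (adjusted p = 0.00875, or an adjusted p of 0.954 with an estimated correlation) and 0 of 14 genes past the threshold, also adjusted over the list alone. Ttr stood at 13.35, 13.07 and 13.48 on the double mutant arrays and at 11.97, 13.24 and 11.39 on the wild type arrays.

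In midbrain at 6 months the apelin receptor gene Aplnr (-1.17 ± 0.205) and Alox8 (-1.06 ± 0.114) fell, and the chemokine gene Ccl28 (1.01 ± 0.230) and the angiotensin receptor gene Agtr2 (1.00 ± 0.101) rose, the largest changes beyond the shared genes among those whose arrays did not overlap between genotypes. Agtr2 and Alox8 passed the threshold in all 11 alternatives, while Ccl28 missed it in 6 of 11 (adjusted p up to 0.223) and Aplnr in 1 of 11 (0.166). The filter on dim probe sets removed all of these genes, so it was not among their alternatives. Their values were not all shown to lie above background. Lower too were Aldh4a1 (-0.99, missed in 1 of 12), Zfp949 (-0.90), Gm9895 (-0.89) and 2810405F15Rik (-0.82). Higher were the sulfotransferase gene Sult2b1 (0.85, missed in 2 of 12), Filip1 (0.79, past the threshold in 6 of 12 alternatives), 4833420G17Rik (0.77) and the interferon-inducible GTPase gene Gbp2b (0.75, missed in 4 of 11 alternatives). In all, 271 probe sets passed the threshold, 125 higher and 146 lower, and 83 genes. Dopaminergic neuron genes in this group had a median of 0.082 (adjusted p = 0.117) and 0 of 19 were past the threshold, while 1 was higher adjusted over the list alone.

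In the lists of midbrain at 6 months, cholesterol synthesis genes were higher as a group, with 14 of 15 positive, a median of 0.148 and an adjusted p of 0.00768 (adjusted p = 0.908 with an estimated correlation). Mural and meningeal fibroblast genes were lower, with a median of -0.24 and an adjusted p of 0.00222 (adjusted p = 0.908 with an estimated correlation). Choroid plexus genes had a median of -1.393 (adjusted p = 0.0206, or an adjusted p of 0.954 with an estimated correlation). In these 3 lists 0 genes passed the threshold singly, and adjusted over the list alone 1 mural gene was higher and 2 were lower. Ttr stood at 8.45, 12.79 and 9.15 on the double mutant arrays and at 12.90, 12.34 and 12.85 on the wild type arrays, the opposite order to that at 6 weeks.

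In striatum at 6 months Cdhr1 was again lower (-2.26 ± 0.178, from 8.17 ± 0.08 to 5.91 ± 0.20, SD, n = 3), as were Uggt2 (-1.32), Pop4, a ribonuclease P subunit (-0.97), 2610528A11Rik (-0.96), C030013G03Rik (-0.95) and 2810405F15Rik (-0.92), with SE from 0.097 to 0.184. Higher were Ccl28 (1.23), the adrenaline-synthesising enzyme gene Pnmt (1.03), S100a10 (0.97), the thyrotropin-releasing hormone receptor gene Trhr (0.88), Smpdl3b (0.86) and Sult2b1 (0.85), with SE from 0.108 to 0.230. Among them Trhr missed the threshold in 3 of 12 alternatives, Sult2b1 in 2 of 12, S100a10 in 1 of 12 and Pnmt and Smpdl3b in 1 of 11. In all, 335 probe sets passed the threshold, 157 higher and 178 lower, and 115 genes. With only the 6 arrays compared in the fit the count was 114, and with a 1.5-fold minimum it was 210.

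In the lists of striatum at 6 months, immediate early genes were higher as a group, with 18 of 20 positive, a median of 0.253 and an adjusted p of 0.0216 (adjusted p = 0.954 with an estimated correlation). Singly Homer1 fell (-0.63 ± 0.072) against the list, and 2 genes rose and 1 fell adjusted over the list alone. The list means per array were 7.66, 8.29 and 8.50 in double mutants and 7.96, 7.82 and 7.89 in wild type, so double mutant replicate 1 lay below every wild type array and the difference came from the other 2. Endothelial genes were lower, with a median of -0.164 (adjusted p = 0.0163, or an adjusted p of 0.908 with an estimated correlation), and so were astrocyte genes, with a median of -0.097 (adjusted p = 0.0217, or an adjusted p of 0.908 with an estimated correlation). Mitochondrial biogenesis and dynamics genes had a median of -0.086 (adjusted p = 0.044, or an adjusted p of 0.908 with an estimated correlation). Of these 3 lists 0 genes passed the threshold singly, and 1 astrocyte gene was lower adjusted over the list alone. With replicate number as a block, 3 of the 4 lists called in striatum at 6 months held.

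Few genes passed the threshold for a genotype difference that changed with age. Of 45037 probe sets, 4928, 3564 and 3841 had an unadjusted interaction p under 0.05 in cerebellum, midbrain and striatum. Smaller changes may therefore have been missed. Kbtbd11 passed the threshold in all 3 tissues, with interactions of 3.16 ± 0.387 in cerebellum, 3.37 ± 0.387 in midbrain and 2.80 ± 0.387 in striatum. In cerebellum its double mutant mean was 5.66 ± 0.67 at 6 weeks and 8.87 ± 0.45 at 6 months, against 8.21 ± 0.06 and 8.26 ± 0.04 in wild type (SD, n = 3). Gpx6 did so in striatum (4.56 ± 0.390), where double mutants went from 4.31 ± 0.61 to 9.28 ± 0.72 and wild type from 8.06 ± 0.23 to 8.47 ± 0.07 (SD, n = 3). Yae1d1 had interactions of 1.29 ± 0.229 in cerebellum and 1.36 ± 0.229 in midbrain by its representative probe set. A further Yae1d1 probe set, with a mean of 6.15, gave 0.36 and 0.29 (adjusted p = 0.352 and 0.645). Another, with a mean of 3.53, had the opposite sign (-0.29 and -0.3, adjusted p = 0.433 and 0.602). Kbtbd11 and Gpx6 passed the threshold in all 17 alternatives, but the other probe set of Kbtbd11, with a mean of 4.05, did not pass it in any tissue (0.01, 0.53 and 0.30 in cerebellum, midbrain and striatum), and Yae1d1 missed it in 2 of 17 in cerebellum and in 11 of 17 in midbrain. Double mutant means of 4.31 for Gpx6 in striatum and 3.58 for Kbtbd11 in midbrain at 6 weeks were not shown to lie above background, so these sizes are uncertain.

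In cerebellum 47 probe sets passed the threshold for the age by genotype interaction, 20 positive and 27 negative, and 14 genes. They included the interleukin receptor gene Il1r1 (1.36), the secretion gene Stxbp2 (1.18), Ccdc115 (-1.27), the nuclear receptor gene Nr0b2 (-1.02), Igsf11 (-0.82) and Psors1c2 (-0.74). Of these, Ccdc115 missed the threshold in 11 of 17 alternatives, Psors1c2 in 11 of 16, Nr0b2 in 7 of 16, Stxbp2 in 5 of 17, Igsf11 in 4 of 17 and Il1r1 in 2 of 17. In midbrain the 4 probe sets past it were those of Kbtbd11, Yae1d1, Lbh (0.89, missed in 12 of 17 alternatives) and Gm8369 (0.70, missed in 11 of 16). In striatum 25 passed, 19 positive and 6 negative, including the complement protease gene Masp2 (1.31), Gimap8 (1.29, missed in 7 of 17 alternatives) and C030013G03Rik (-1.46, missed in 2 of 16). All group means of Masp2 in striatum (3.19 to 4.07), Gm8369 in midbrain (2.57 to 3.02) and Psors1c2 in cerebellum (2.63 to 3.13) were below 4.49. So was the double mutant mean of C030013G03Rik in striatum at 6 months (4.25). These means were not shown to lie above background, so the sizes of these interactions are uncertain. Without 1 array the cerebellum count was 93, 22 and 16 (wild type 6-week replicates 1, 2 and 3), 71 and 20 (wild type 6-month replicates 1 and 3), 29 (double mutant 6-week replicate 1), or 76 and 27 (double mutant 6-month replicates 1 and 3). The midbrain count was 15, 1 and 1 (wild type 6-week replicates 1, 2 and 3), 1 and 1 (wild type 6-month replicates 1 and 2), 2 and 2 (double mutant 6-week replicates 2 and 3), or 11 and 1 (double mutant 6-month replicates 2 and 3). The striatum count was 13 and 15 (wild type 6-week replicates 2 and 3) or 11 and 16 (wild type 6-month replicates 1 and 2). Without the arrays with a strong Xist signal the counts were 82, 17 and 44 in cerebellum, midbrain and striatum, and a trend with a robust prior gave 79 in cerebellum. With replicate number as a block the counts were 33, 2 and 12 in the same order.

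**Figure D4:**
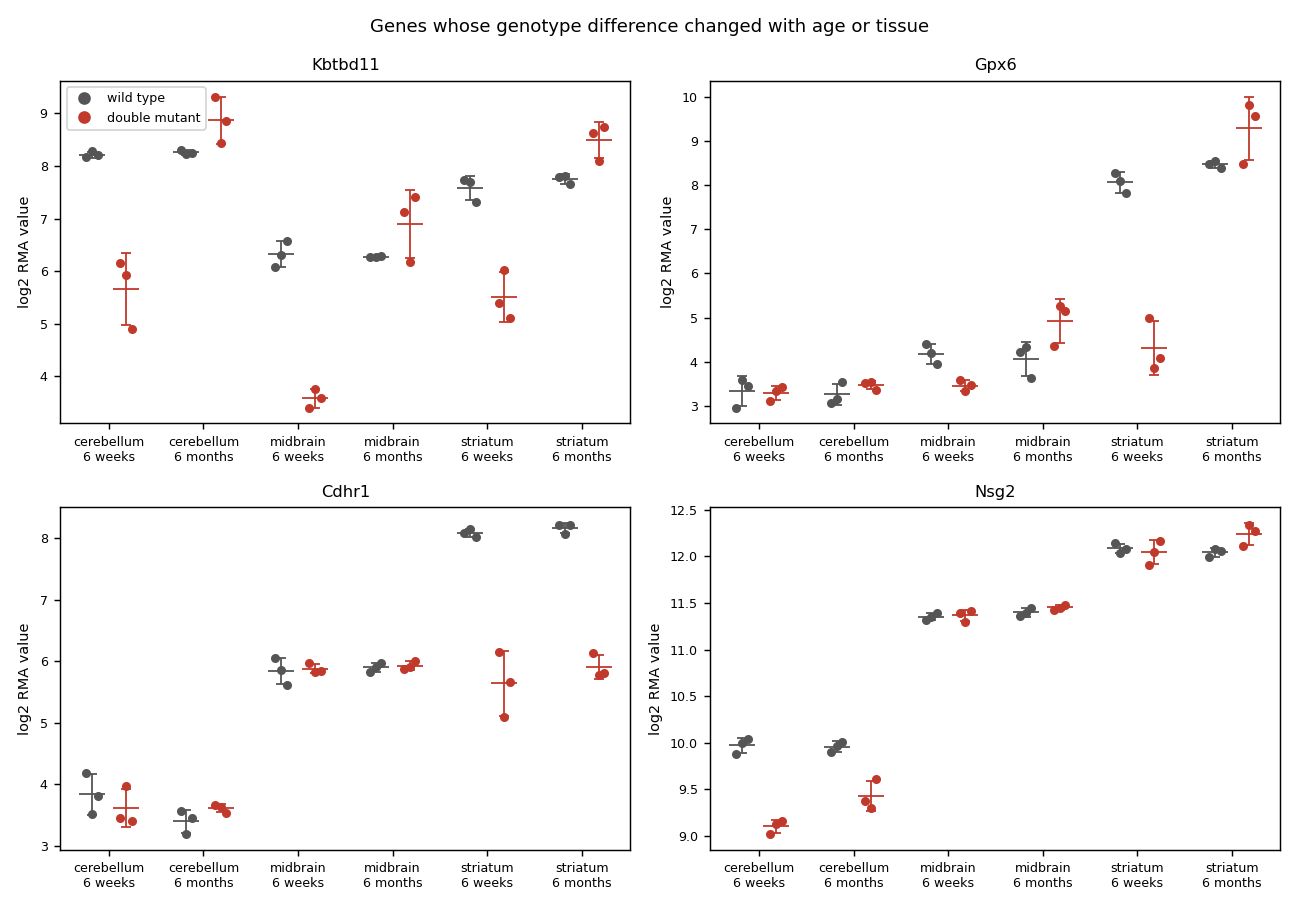
Log2 RMA values per array (vertical axis) of Kbtbd11, Gpx6, Cdhr1 and Nsg2 by tissue and age (horizontal axis), in wild type (grey) and double mutant (red). Points are arrays, horizontal marks are means and bars are SD (n = 3). In striatum the double mutant mean of Gpx6 was 4.31 at 6 weeks and 9.28 at 6 months, and that of Cdhr1 stayed below wild type at both ages.

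The genotype difference of other genes depended on the tissue. Cdhr1 was lower in striatum by 2.35 on the log2 scale (-2.35 ± 0.126), against 0.00 ± 0.126 in cerebellum and 0.03 ± 0.126 in midbrain, averaged over ages (adjusted p of the F test 2.98e-10). Its cerebellum arrays ran from 3.19 to 4.19 and were not shown to lie above background. The value of 0.00 there therefore does not show that the genotypes are alike. Nsg2, a neuronal vesicle protein gene, was lower in cerebellum (-0.70 ± 0.053), against 0.04 in midbrain and 0.07 in striatum (adjusted p = 1.12e-07). Homer1 was lower in striatum (-0.54 ± 0.051) and midbrain (-0.28 ± 0.051), against 0.12 ± 0.051 in cerebellum, and Alox8 was lower in midbrain (-1.09 ± 0.081), where Agtr2 was higher (0.75 ± 0.072), with an adjusted p of 1.81e-05 for each of the 3 genes. Rragd was higher in all tissues and most in cerebellum (0.88, 0.36 and 0.27 in cerebellum, midbrain and striatum, adjusted p = 8.85e-05). Klhl1 was higher in cerebellum (0.39 ± 0.105) and lower in striatum (-0.78 ± 0.105, adjusted p = 9.44e-05), and Uggt2 was lower in all and most in striatum (-0.54, -0.63 and -1.25, adjusted p = 0.000142). In all, 93 probe sets and 41 genes passed the threshold. The count was 414 without midbrain wild type 6-week replicate 1, 154 without the arrays with a strong Xist signal, 53 with replicate number as a block, and 40 after dim probe sets were left out.

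With age in wild type mice, the myelin and cholesterol synthesis lists were lower as groups in all 3 tissues at the preset correlation, but only in midbrain with an estimated correlation. Among genes past the threshold, the membrane transporter gene Abca8a rose most in each, by 1.69 ± 0.163 in cerebellum, 1.99 ± 0.163 in midbrain and 1.63 ± 0.163 in striatum. Of 14 myelin genes 4, 5 and 3 fell in cerebellum, midbrain and striatum (9, 13 and 3 adjusted over the list alone), with medians of -0.399, -0.519 and -0.268 and adjusted p of 2.87e-09, 2.52e-26 and 0.00194. With an estimated correlation the adjusted p values were 0.226, 0.0366 and 0.631. Of 15 cholesterol synthesis genes 7, 1 and 3 fell (11, 10 and 5 adjusted over the list alone, with 1 rise in striatum), with medians of -0.376, -0.288 and -0.21 and adjusted p of 9.21e-12, 2.73e-15 and 0.00382. With an estimated correlation these adjusted p values were 0.0586, 0.0366 and 0.561. The falls included Fa2h, which makes myelin lipids (-0.80, -0.85 and -0.74), and in cerebellum the sterol enzyme gene Sqle (-0.92 ± 0.092) and Cyp51 (-0.55 ± 0.104).

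The oligodendrocyte precursor list was lower with age as well, led by Gpr17 (-0.91, -0.85 and -0.74, SE 0.119). Of 10 genes 2, 2 and 3 fell (3, 3 and 3 adjusted over the list alone) and Lhfpl3 rose in striatum (0.47 ± 0.132, 1 rise by either adjustment). The list medians were -0.228, -0.165 and -0.24 and the adjusted p values 0.0171, 6.21e-05 and 0.0392, which with an estimated correlation became adjusted p values of 0.429, 0.121 and 0.549. Extracellular matrix collagen genes fell in cerebellum (4 of 16, 8 adjusted over the list alone, median -0.31, adjusted p = 9.88e-07) and in midbrain (1 of 16, 4 adjusted over the list alone, median -0.2, adjusted p = 2.52e-06), led by Col3a1 (-1.64 and -1.40). With an estimated correlation the adjusted p was 0.0586 in both. Genes of the endoplasmic reticulum unfolded protein response rose as a group, with medians of 0.311, 0.173 and 0.213 and adjusted p of 2.91e-08, 0.00105 and 0.044 (adjusted p = 0.226, 0.594 and 0.779 with an estimated correlation). Of 18 genes 3 rose in cerebellum, including Herpud1 (0.58 ± 0.124), and 0 in the other tissues (9, 3 and 2 adjusted over the list alone).

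Immune lists rose with age in some wild type tissues. Interferon response genes rose in striatum (median 0.223, adjusted p = 0.0105, 2 of 15 past the threshold and 3 adjusted over the list alone), where Xaf1 rose by 0.80 ± 0.106 and Ifit3 by 0.72 ± 0.196, and in midbrain (median 0.23, adjusted p = 0.0104, 0 past it and 2 adjusted over the list alone). With an estimated correlation the adjusted p was 0.355 in both. Antigen presentation genes of MHC class I rose in cerebellum (median 0.137, adjusted p = 0.0208, 1 of 10 by either adjustment, H2-T10 at 0.63 ± 0.114) and in midbrain (median 0.206, adjusted p = 0.00455, 0 past the threshold and 2 adjusted over the list alone), with adjusted p of 0.226 and 0.121 with an estimated correlation. Microglia genes rose as a group in midbrain (median 0.197, adjusted p = 0.00433, 0 of 17 singly and 4 adjusted over the list alone, adjusted p = 0.526 with an estimated correlation).

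Other lists changed with age in 1 or 2 of the wild type tissues. Immediate early genes fell in striatum, where Arc, which acts at synapses, fell by 1.06 ± 0.210 (median -0.292, adjusted p = 0.0382), and in midbrain (median -0.136, adjusted p = 0.0423), with an adjusted p of 0.779 in both with an estimated correlation. In striatum 2 of 20 fell and 1 rose (4 and 1 adjusted over the list alone), and in midbrain 0 passed by either adjustment. Immature neuron genes fell in striatum (3 of 16 by either adjustment, including Sox4 at -0.39 ± 0.068 and Dlx2 at -0.50 ± 0.124, median -0.202, adjusted p = 0.00718, adjusted p = 0.271 with an estimated correlation), and mitochondrial biogenesis genes rose there (3 of 20, including Dnm1l, the mitochondrial fission gene, at 0.27 ± 0.054, with 4 rises and 1 fall adjusted over the list alone, median 0.087, adjusted p = 0.0253, adjusted p = 0.429 with an estimated correlation). In cerebellum the cytosolic heat shock list rose (median 0.14, 0 of 13 singly and 2 adjusted over the list alone, adjusted p = 0.00465, adjusted p = 0.631 with an estimated correlation), as did the Parkinson disease list, in which Lrrk2 rose by 0.41 ± 0.104 (median 0.07, 1 of 15 singly, 5 rises and 1 fall adjusted over the list alone, adjusted p = 0.0226, adjusted p = 0.226 with an estimated correlation). The choroid plexus list went down in cerebellum (median -1.093, adjusted p = 0.0127) and up in midbrain (median 1.792, adjusted p = 0.00194), with adjusted p of 0.745 and 0.631 with an estimated correlation, 0 of 14 singly in either, and 1 fall and 3 rises adjusted over the list alone.

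In wild type cerebellum 1119 probe sets passed the threshold with age, 595 higher and 524 lower at 6 months, and 412 genes. Among the largest rises were the clock gene Per2 (1.64 ± 0.249), Ctxn3 (1.49), the cytokine gene Il33 (1.23), Ltbp2 (1.16) and Fam163b (1.01), and among the largest falls Col3a1, the vascular gene Apold1 (-1.32), the myosin-binding gene Mybpc3 (-1.23), Ccnd2, a cyclin (-1.09), Mkrn3 (-0.96) and Ntng2 (-0.95). The count was 584, 654 and 517 without 6-week replicates 1, 2 and 3, 547 and 355 without 6-month replicates 2 and 3, 337 with only the 6 wild type arrays in the fit, 290 with a 1.5-fold minimum, and 683 without the arrays with a strong Xist signal. Apold1 missed the threshold in 8 of 13 alternatives and Ntng2 in 7 of 13. In wild type midbrain 112 passed, 29 higher and 83 lower, and 40 genes. Rises included Exoc3l4 (1.02), Dmp1 (0.86), the Notch target gene Hes1 (0.79), the antiviral gene Zc3hav1 (0.74) and Mvp, the major vault protein gene (0.73), and falls 9630013A20Rik (-1.46), Col3a1, the kinase gene Sgk2 (-0.94), Fa2h, Gpr17 and the myelin gene Tspan2 (-0.83). The midbrain count was 222, 30 and 40 without 6-week replicates 1, 2 and 3, 44, 37 and 48 without 6-month replicates 1, 2 and 3, 28 with only the 6 wild type arrays in the fit, 64 with a 1.5-fold minimum, and 212 without the arrays with a strong Xist signal. Mvp missed the threshold in 7 of 12 alternatives, Sgk2 in 7 of 13, Dmp1 and Hes1 in 6 of 13, Zc3hav1 in 5 of 13, Col3a1 in 2 of 13, Gpr17 in 1 of 13 and Exoc3l4 in 1 of 12.

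In wild type striatum 2618 probe sets passed the threshold with age, 1110 higher and 1508 lower, and 1233 genes. Rises included the Wnt agonist gene Rspo1 (1.39 ± 0.160), Il33 (1.11), the matrix gene Efemp1 (1.02), Shisa2 (0.95) and A230009B12Rik (0.92), and falls Apold1 (-1.30), the glutamate receptor auxiliary gene Cnih2 (-1.10), Arc, Tmem163 (-1.02), Marcksl1 (-1.02) and Tcfl5 (-0.99). The count was 1269 and 1190 without 6-week replicates 2 and 3, 1384 and 1412 without 6-month replicates 1 and 2, 685 with only the 6 wild type arrays in the fit, and 443 with a 1.5-fold minimum. There Apold1 missed the threshold in 5 of 13 alternatives, Shisa2 in 4 of 13, Tcfl5 in 4 of 12, Tmem163 in 1 of 13 and A230009B12Rik in 1 of 12. Of the probe sets past the threshold in wild type, 960 of 1119 (85.8%) in cerebellum, 97 of 112 (86.6%) in midbrain and 2362 of 2618 (90.2%) in striatum changed with the same sign in double mutants, whose arrays are separate. Past the threshold in both genotypes and in the same direction were 317, 44 and 737 probe sets, against 20.2, 0.347 and 53.3 for independent lists. The lists share 1 estimate of the spread per probe set. A batch of arrays by age, or the strong Xist signal of replicate 1 at 6 weeks, would be common to both genotypes. The agreement therefore does not separate these from age.

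The labels give neither the sex of the animals nor an array batch. Replicate 1 of each of the 6-week groups, 6 arrays in all, had Xist values of 10.01 to 11.25 and Eif2s3y values of 2.38 to 2.79, while the other 30 arrays had 3.42 to 4.17 and 7.0 to 8.66. Both genotypes were alike in this at each age, but the 2 ages were not, so the age differences include arrays of a different Xist signal. Age and any batch of arrays cannot be told apart in either genotype. Differences between genotypes in the ratio of 3' to 5' control signals gave two-sided exact permutation p values from 0.1 to 0.9 over the 6 combinations of tissue and age and 2 control transcripts, with 0.1 the smallest value that 3 arrays against 3 allow. The Gapdh difference was negative in double mutants in all 6 combinations (-0.02 to -0.08) and the Actb difference in 5 of 6 (-0.08 to 0.06).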

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

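The test of sex as a source of shared variation, the fits without arrays of strong Xist signal, the list tests without genes beside Pink1, the choice of the 500 most variable genes, and the margins added to the bounds for cell types, RNA handling and segregating alleles, and the splits with the common change with age subtracted were chosen after the results were seen. The other tests here were written down beforehand.

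The genotype difference changed with age at 47 probe sets in cerebellum, 4 in midbrain and 25 in striatum, by the test of the interaction. The genes named by the rule were Kbtbd11 (3.16, 3.37 and 2.80 in cerebellum, midbrain and striatum), Yae1d1 (1.29 in cerebellum and 1.36 in midbrain), Il1r1 (1.36), Stxbp2 (1.18), Ccdc115 (-1.27), Nr0b2 (-1.02), Igsf11 (-0.82) and Psors1c2 (-0.74) in cerebellum, Lbh (0.89) and Gm8369 (0.70) in midbrain, and Gpx6 (4.56), Masp2 (1.31), Gimap8 (1.29) and C030013G03Rik (-1.46) in striatum. Leaving out 1 array moved these counts, from 16 (without wild type 6-week replicate 3) to 93 (without wild type 6-week replicate 1) in cerebellum, from 1 (without wild type 6-week replicate 2, among others) to 15 (without wild type 6-week replicate 1) in midbrain, and down to 11 (without wild type 6-month replicate 1) in striatum. The genotype difference depended on the tissue at 93 probe sets, or 414 without midbrain wild type 6-week replicate 1. The adjusted p of that F test was 2.98e-10 for Cdhr1, 1.12e-07 for Nsg2, 1.81e-05 for Homer1, Agtr2 and Alox8, 8.85e-05 for Rragd, 9.44e-05 for Klhl1 and 0.000142 for Uggt2.

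Many genotype differences were shared by all tissues and ages, and 60.2% of the genes past the threshold in the average had another such gene among the 5 nearest on either side, above the 43.2% that 0.1% of random sets exceeded, while the shares for age in wild type lay below such values (24.9% against 29.6% in cerebellum and 57.2% against 57.6% in striatum, although 0.29% of random sets reached the latter share), as did that for the genotype difference in striatum at 6 weeks (19.2% against 20.3%). This is what genomic segments of different parental strain may leave, since the labels give the strains of the controls and not those of the double mutants, and the excess beside Pink1 (one-sided Fisher exact p = 0.000467) goes the same way, although 4.84% of genes have flanks with at least that share. Sequence differences under single probes stay open, because a second probe set moved the same way with an unadjusted p under 0.05 in 46.9% of 213 genes, between the 2 bounds set in advance. For age in wild type, where strain does not differ, this share was 57.7%, 91.7% and 46.5% in cerebellum, midbrain and striatum, so it does not discriminate. A second probe set moved the opposite way with an unadjusted p under 0.05 in 26 of the 213 genes. For age it did so in 4 of 149, 0 of 12 and 6 of 404. A different mix of cell types would have been excluded by the bound as first written, since the largest list median was 0.104 against 0.124, but is left open because the bootstrap interval of the blood list reached 0.47. An effect of the mutations themselves on these genes remains open and cannot be separated from strain in this design.

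Over the probe sets called for the age by genotype interaction, the absolute change with age in wild type was 0.344 of that in double mutants (median, 95% bootstrap interval 0.244 to 0.574). By the bound as first written this ratio excluded an age batch of arrays common to both genotypes, but it decides nothing, because the probe sets were selected for an unequal change and a shift common to both genotypes cancels in the interaction. Different alleles carried by the double mutants of the 2 ages could account for genes such as Kbtbd11, which moved alike in all 3 tissues. Over all called probe sets 57.9% had the same sign in both other tissues with an unadjusted p under 0.05 in at least 1, between the bounds set in advance, so that alleles and an effect of age in double mutants cannot be told apart.

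The splits of the age by genotype interaction exchanged ages within each genotype and so turned a change with age common to both genotypes into an interaction. They gave as many probe sets in 13, 16 and 20 of 100 in cerebellum, midbrain and striatum, with highest other counts of 870, 475 and 5336, and do not decide about chance. With the common change with age subtracted from the values, 2 of 100 splits gave as many as 47 in cerebellum (highest other 66). These include the real one, and the share is under 0.05, but this test was chosen after the results were seen. It was also run in 3 tissues without adjustment, so chance is argued against in cerebellum but not excluded. In midbrain 6 of 100 gave as many as 4 (highest other 7) and in striatum 8 of 100 gave as many as 25 (highest other 479), so chance was not excluded in these tissues. The count of 479 came from a split that kept 2 of 3 arrays of each genotype at their age, and what produced it was not tested.

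Double mutant arrays with the same replicate number deviated together across tissues, with mean correlations of 0.233 at 6 weeks and 0.194 at 6 months, each the highest of the 36 ways to match the numbers, while in wild type 0.122 at 6 weeks was also the highest (highest other 0.119) and -0.019 at 6 months was not. Sex is argued against as the whole source in double mutants, since the correlation of 0.194 at 6 months arose where no array had a strong Xist signal, and stays open in wild type, where only the age with such arrays gave the highest value. Alleles that segregate among the double mutant animals may contribute: of the 500 genes that differed most between double mutant animals at 6 months, 33% had another of them among the 5 nearest on either side, against 28.4% in wild type. By the rule as first written, this share, below the 34% that 0.1% of random sets exceeded, excluded segregating alleles and favoured RNA handling or an array batch shared by the tissues of an animal. Because it also lay above the 30.8% that 2.5% of random sets exceeded, both are left open here, and the labels do not say whether tissues with 1 number came from 1 animal.

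Splits of 3 arrays against 3 number 10, too few for a share under 0.05, and the real split gave the largest count in 1 of 10 in each of the comparisons that follow. The real and highest other counts for the genotype difference at 6 weeks were 484 and 1 in cerebellum, 442 and 3 in midbrain, and 546 and 415 in striatum. At 6 months they were 711 and 1, 271 and 1, and 335 and 5. For age in wild type they were 1119 and 2 in cerebellum, 112 and 24 in midbrain, and 2618 and 183 in striatum. The split with 415 probe sets placed both striatum arrays with a strong Xist signal on 1 side. Splits that did so at 6 weeks gave at most 3 in midbrain and 1 in cerebellum, so this signal alone was not shown to account for the 415. For the averaged genotype difference 1 of 100 splits, the real one, gave as many as 1989. The highest other count was 920, so chance was excluded there. For the tissue by genotype interaction 1 of 100 gave 93, with 40 the highest other. These splits mixed the genotypes, so a genotype difference common to the tissues entered the spread within groups. That could lower the other counts, so the splits do not decide about chance for this interaction.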

How the results depend on the processing

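The fits without arrays of strong Xist signal, those with Xist as a covariate, the list tests without genes beside Pink1 and the renormalised tissue markers were chosen after the data were seen, and the other alternatives were planned. No result changed direction, and both Pink1 probe sets passed the threshold in all 238 alternative values. The cause of a changed count was not tested unless the setting itself gives it, such as fewer arrays in the fit or a stricter threshold.

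With a 1.5-fold minimum added, the genotype counts were 278, 280 and 300 at 6 weeks (cerebellum, midbrain, striatum), 292 in cerebellum and 210 in striatum at 6 months and 221 in the average, and the wild type age counts were 290, 64 and 443. With only the 6 arrays compared in the fit, the genotype counts were 269, 240 and 345 at 6 weeks and 211 (cerebellum) and 114 (striatum) at 6 months, and the wild type age counts were 337, 28 and 685. Without arrays of strong Xist signal the counts were 666 for midbrain at 6 weeks, 82, 17 and 44 for age by genotype in cerebellum, midbrain and striatum, 154 for tissue by genotype, and 683 and 212 for wild type age in cerebellum and midbrain. Leaving out dim probe sets gave 40 for tissue by genotype, and a trend with a robust prior gave 79 for age by genotype in cerebellum.

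Arrays with the same replicate number showed little joint deviation between genotypes (correlations of -0.17 to 0.21, 5 of 18 over 0.1), although replicate 1 of both genotypes at 6 weeks shared a strong Xist signal in each tissue. The replicate block gave 53 for tissue by genotype and 2 and 12 for age by genotype in midbrain and striatum, and changed no other count by over 1.5 times. A random block on genotype, age and number across tissues had a consensus correlation of 0.0602 and gave 1727 probe sets in the average (1989 without it) and 112 for tissue by genotype (93 without it).

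Leaving out each array of the groups compared in turn gave ranges of 299–448, 221–968 and 324–540 at 6 weeks, 348–853, 199–256 and 248–377 at 6 months, 1822–2060 in the average, 16–93, 1–15 and 11–31 for age by genotype, 67–414 for tissue by genotype, and 355–1065, 30–222 and 1190–3235 for wild type age. The values 968, 15, 414 and 222 came without midbrain wild type 6-week replicate 1. Of the named genes' values in these fits 1846 stayed past the threshold and 158 did not. For list tests, 2 of 51 calls held with an estimated correlation, myelin and cholesterol synthesis with age in wild type midbrain, 49 with the replicate block and 39 with the mean over a gene's probe sets. That mean gave 0, 3 and 1 lists for genotype at 6 weeks in cerebellum, midbrain and striatum, against 4, 3 and 2. At 6 months it gave 5, 2 and 2 against 4, 3 and 4, and in the average 3 against 4. Without the genes beside Pink1, 2 of 5 calls held, and respiratory complexes II to V, not called in the average before, were called lower there (adjusted p = 0.0499). On arrays the signal over background limits dim genes, and raw intensities were not available.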

Other observations

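Choroid plexus content differed between single arrays of 1 group. Ttr ran from 8.45 to 13.48 over all arrays, and from 8.62 to 13.25 among the 3 double mutant cerebellum arrays at 6 weeks alone. In wild type striatum at 6 weeks replicate 1 was at 12.97 and the other arrays at 8.80 and 9.56. The mean of the 14 choroid plexus and ependyma genes followed it, at 6.60 against 4.67 and 4.64.

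Many of the genes that changed most with age in wild type changed likewise in double mutants, whose arrays are separate. The difference in Xist signal between the ages was common to both genotypes, and a batch by age could be. Abca8a rose by 1.5 in cerebellum, 1.82 in midbrain and 1.49 in striatum of double mutants, Per2 by 1.77 in cerebellum, Rspo1 by 1.3 in striatum, and Gpr17 fell by 0.90 in midbrain. Of the 36 values, 12 for each tissue, 9 did not pass the threshold in double mutants. They were Apold1 in cerebellum (0.03, adjusted p = 0.982) and striatum (-0.37, adjusted p = 0.687), Ccnd2 in cerebellum (-0.26, adjusted p = 0.392), Arc in striatum (-0.58, adjusted p = 0.128), and in midbrain Exoc3l4 (-0.03), Hes1 (0.26), Zc3hav1 (0.10), Mvp (-0.17) and Sgk2 (-0.50). None of them passed the test of the age by genotype interaction, so a difference between genotypes in their change with age was not shown.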
